A study of Mus musculus with 7 samples.

How the data were processed

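The study profiled CD45-positive, DRAQ7-negative cells sorted from the brains of female mice with GL261 tumours at day 21 by droplet single-cell RNA-seq. Treatment began on day 7 per the labels. Each group held 4 mice, cells were pooled from 2 mice per library (5000 cells per mouse), and 7 libraries of 14 mice were analysed. PT2385 was given at 10 mg/kg per the labels. The protocols describe vehicle and isotype controls without saying which the untreated mice received. The deposited files hold UMI counts of 32285 genes for barcodes that the authors had already called as cells, with 40 symbols used more than once. Per the submitters' processing notes the counts were made with Cell Ranger 2.2.0 against GRCm39, while the file headers name version 7.0.0. The notes also describe clustering in Seurat 5, which was not used here.

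Barcodes with at least 300 genes and at most 10% mitochondrial UMIs were kept (40416 of 41033). Doublets were scored per library with Scrublet (expected rate 5%) in scanpy 1.11.5. Its automatic threshold marked only 11 cells, so the cells with the highest scores were removed at 0.8% per 1000 barcodes of the library. This rate was chosen after the data were seen, and removed 1948 cells. Counts were scaled to 10000 per cell and log-transformed. 3000 variable genes, 50 principal components and 15 neighbours were used for Leiden clustering at resolution 1, without integration of libraries. T and NK clusters, and mononuclear myeloid clusters, were each clustered again in the same way. Clusters were named from fixed marker lists, counting a marker as detected in at least 10% of cells and asking for at least 3 markers. Clusters whose leading genes match no list stayed unnamed. The suffix "-like" marks that names rest on transcripts. Libraries of a group are called pool 1 and pool 2 in the order of their records.

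Cells per class and library were tested with the edgeR 4.0.16 quasi-likelihood test over 22 classes. For genes, counts were summed per library and class for the 7 classes with at least 30 cells in each library, normalised with TMM, filtered with filterByExpr and tested with the same tool, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Effects of PT2385 and of ICB come from an additive model with 4 residual degrees of freedom, each comparing 4 libraries with 3. The combination against ICB, the combination against untreated, and the interaction come from a model with 1 mean per group and 3 residual degrees of freedom. Standard errors were taken as the absolute log2 fold change over the square root of the F statistic. An exact permutation test of shares can give no p below 0.0286 for 4 against 3 libraries and 0.333 for 2 against 2.

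28 gene lists were fixed in advance, and those with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusting over lists within a class and comparison. Of 652 list tests 231 passed with the preset correlation, 0 with an estimated one and 16 with the rotation test fry. In each comparison and class, the genes named are those with adjusted p under 0.05 and a mean of at least 20 CPM that have the 4 largest rises and the 4 largest falls. Where fewer than 3 passed, the 3 with the smallest p were considered. Drug-target genes and the leading members of passing lists were added. Variable segments of antigen receptors were not named. The report gives part of the genes so named. A ratio with 1 to 3 counts in a group carries an exact 95% interval, which covers the counting of UMIs and not the spread between libraries, and a group without counts was set to 3 counts.

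The libraries held 59839154 to 81960504 UMIs and 4656 to 7446 kept cells. At this depth a share of 0 in the untreated library has an upper limit of 0.0403%. The tests were tried on simulated data with 200 changed genes per class, 100 of them for each fold. A 2-fold change was recovered in 65 to 81% of genes for PT2385, 55 to 73% for ICB, 42 to 67% for the combination against ICB, 30 to 45% for the combination against untreated and 9 to 27% for the interaction. A 4-fold change was recovered in 87 to 95%, 85 to 97%, 77 to 90%, 74 to 89% and 57 to 73%. A 4-fold change of 1 class share, that of NK-like cells, was recovered in 98 of 100 simulations at a dispersion set by hand. Simulated genes had the trended dispersion of their class, without spread of single genes around it, pools that stand apart or shifts in the mix of clusters. Recovery in the real data can therefore be lower than these rates.

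Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, doublets kept, a strict cell filter (500 genes, 5% mitochondrial UMIs, 35558 cells), Leiden resolution 2, other models, each library left out in turn, fry and an estimated correlation for lists, and for shares TMM factors, a denominator of named immune classes and the exact test. After the clusters were seen, fits without clusters M15, M17 or T15, of CD8 T-like cells without their cluster led by Gzmf at resolution 2, fits of M10 alone, and the 19 classes with a mean of at least 10 cells were added. A count moving less than 1.5-fold was taken as the same. Antigen receptors, splicing and variants were not analysed here. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 with fixed seeds. Some gene results that the naming rule or a list test gives are not reported here.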

Results

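The data are single-cell transcriptomes of leukocytes from mouse brains carrying GL261 glioma. Per the labels, living CD45-positive cells were sorted 21 days after implantation. Mice were untreated, or received the HIF-2α inhibitor PT2385, immune checkpoint blockade (ICB, antibodies to PD-1 and TIM-3), or both. The 7 libraries analysed are 1 of untreated mice and 2 of each treated group, and each library is a pool of 2 mice. A second untreated pool was not analysed here. PT2385 blocks a protein and the antibodies bind surface proteins, so no transcript shows that a treatment reached its target. Epas1, which encodes HIF-2α, stayed below a mean of 20 CPM (counts scaled to the library total) in each of the 7 classes tested for genes.

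Library sizes were similar enough for all 7 to be compared. They held 4926 to 8080 barcodes and 59839154 to 81960504 UMIs, and 38468 of 41033 barcodes were kept. The untreated library gave the most cells (7446 kept) and the lowest median depth (8088 UMIs per cell), and PT2385 pool 1 the highest (11678.5). Values below are means ± SD over pools, or log2 fold changes ± SE. Adjusted p-values of genes and of class shares come from edgeR with Benjamini-Hochberg adjustment, and those of gene lists from camera. Those of edgeR measure the spread between pools, and comparisons with untreated mice assume that the lone untreated library varies like the others. Those of camera set a list against the other genes at a preset correlation, and with an estimated one no list passed. Where a gene is said not to pass without a library, that fit is an example, and its call can be lost without others too. Unless another number is given, a gene that rose or fell lay on that side of the reference mean in each treated library (4 of 4 for the effect of 1 treatment, 2 of 2 for the combination).

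Microglia-like cells were most frequent and monocyte/macrophage-like cells least frequent in mice given both treatments. Microglia-like cells made up 6.03% of the untreated library (exact 95% interval 5.50 to 6.60%), 10.5 ± 0.615% with PT2385, 12.4 ± 0.311% with ICB and 29.6 ± 4.76% with both. Monocyte/macrophage-like cells made up 53.7%, 53.0 ± 3.39%, 42.7 ± 14.1% and 23.9 ± 1.07% in the same order. The ICB pools stood apart in the latter class, at 32.7% and 52.6%. No class share passed for PT2385. The difference in microglia-like cells was 1.07 ± 0.33 (edgeR adjusted p = 0.185) and that in monocyte/macrophage-like cells −0.52 ± 0.37 (edgeR adjusted p = 0.409). For ICB the microglia-like difference of 1.31 ± 0.33 stayed just short of passing over all 22 classes (edgeR adjusted p = 0.0560), and passed over the 19 classes with a mean of at least 10 cells (edgeR adjusted p = 0.0354). It did not pass with TMM factors (1.26, edgeR adjusted p = 0.110) or by the exact permutation test (p = 0.114, adjusted p = 0.419). Both treatments against none gave 2.29 ± 0.50 (edgeR adjusted p = 0.0510 over 22 classes, 0.0282 over 19). Both against ICB alone gave 1.26 ± 0.37 for microglia-like and −1.25 ± 0.37 for conventional dendritic-like cells (edgeR adjusted p = 0.134 for each).

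**Figure D1:**
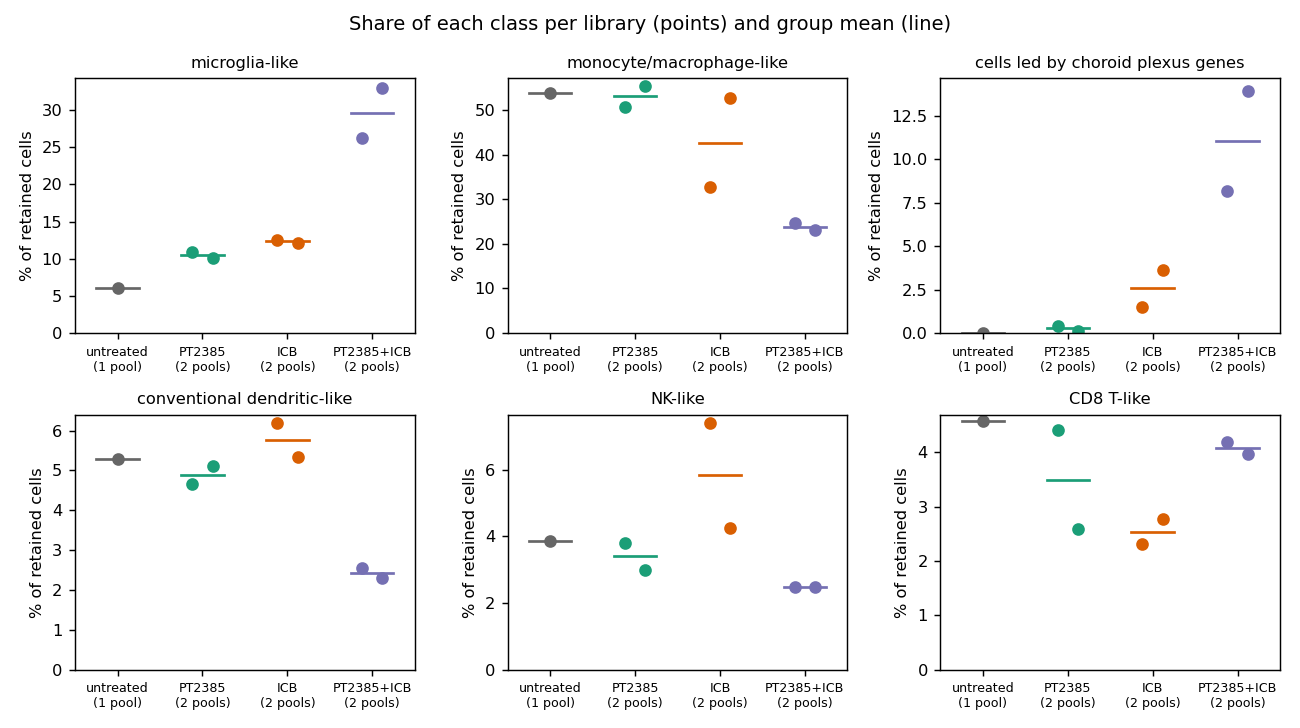
Share of retained cells in each class, 1 point per library, by treatment group. Each point is a pool of 2 mice.

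The only share that passed over all classes belonged to cells led by choroid plexus genes such as Ttr, an unnamed class outside the leukocytes. None of 7446 untreated cells belonged to it, against 0.280 ± 0.201% with PT2385, 2.57 ± 1.53% with ICB and 11.1 ± 4.07% with both. The 2 ICB pools held 1.48% and 3.65% and the 2 combination pools 8.18% and 13.9%. The rise with ICB was 5.94 ± 0.97 (edgeR adjusted p = 0.0125). The call was lost without PT2385 pool 2 (5.73, edgeR adjusted p = 0.135) and without combination pool 2 (5.94, edgeR adjusted p = 0.0590). Against the floor of 3 cells the share was at least 274-fold higher with both treatments than without (edgeR adjusted p = 0.0215), and leaving out combination pool 1 (edgeR adjusted p = 0.0544) or pool 2 (edgeR adjusted p = 0.0653) ended the call. An exact permutation test of 4 against 3 libraries gave p = 0.0286 for this class with ICB, the smallest value the design allows, and 0.314 after adjustment. Gamma-delta T-like cells gave the same permutation p of 0.0286 with ICB (edgeR adjusted p = 0.152), and no lymphoid share passed after adjustment. CD8 T-like cells made up 4.57% of the untreated library, 3.49 ± 1.29% with PT2385, 2.53 ± 0.327% with ICB and 4.07 ± 0.164% with both, and regulatory T-like cells 4.94%, 2.96 ± 0.338%, 3.33 ± 1.51% and 2.69 ± 0.850%.

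With PT2385 granzyme B transcripts fell in CD8 T-like and regulatory T-like cells, and Cd200r1, which encodes an inhibitory receptor, rose in CD8 T-like and NK-like cells. Of the 40 gene results named by the fixed rule for this treatment, 17 rose and 23 fell. 7 of them passed in every fit that left out 1 library.

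In monocyte/macrophage-like cells 125 of 15126 genes passed with PT2385 (33 rose, 92 fell). Leaving out the untreated library left 0 (edgeR), with 3198 at unadjusted p under 0.05 and 1054 by DESeq2 when all 7 were used. Leaving out ICB pool 2 gave 1160. Spp1 (osteopontin) fell by 1.92 ± 0.18, from 101 ± 33.5 to 24.7 ± 4.3 CPM (edgeR adjusted p = 0.0280). Pf4, a chemokine of border-associated macrophages, fell by 2.38 ± 0.34 (edgeR adjusted p = 0.0477), and the monocyte attractant Ccl12 by 1.47 ± 0.21, from 434 ± 129 to 158 ± 17.9 CPM (edgeR adjusted p = 0.0476). S100a4, a calcium-binding protein of motile cells, fell by 1.47 ± 0.17 (edgeR adjusted p = 0.0309). Without the untreated library the same 4 genes lay at −2.09, −2.12, −1.36 and −1.44 (edgeR adjusted p = 0.248, 0.306, 0.306 and 0.306). The genes that rose most were the interferon-inducible GTPase Gm4951 (1.28 ± 0.18, edgeR adjusted p = 0.0476) and the actin regulator Cyfip2 (0.88 ± 0.09, edgeR adjusted p = 0.0176), which were lost in the same fit at 1.27 and 0.95. Nos2, the inducible nitric oxide synthase, was higher without passing (2.98 ± 0.50, edgeR adjusted p = 0.0601), at 434 and 300 CPM in the 2 pools with PT2385 alone and 50 in the untreated library. The mix of clusters in the class differed between libraries. Cluster M0 made up 28.2% in the untreated library and 4.1% and 5.9% with PT2385 alone, M8 (led by Nos2) 6.1% against 27.5% and 19.9%, and M5, with Pf4 among its leading genes, 46.4% in ICB pool 1 and at most 2.7% elsewhere.

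Among the fixed lists, type I interferon genes were lower as a set in monocyte/macrophage-like cells. Cluster M3 of this class is led by the interferon-induced Rsad2, Ifit2 and Ifit3. It made up 6.1% of the class in the untreated library and 8.8% and 3.8% with ICB. It made up 2.0% and 3.8% with PT2385 alone and 3.2% and 1.7% with both. The list was not tested without M3. Of 28 tested members 1 fell over all genes (Slfn5, −0.62 ± 0.11, edgeR adjusted p = 0.0493) and 25 fell adjusted over the list alone (camera adjusted p = 1.09e-12, adjusted p = 0.651 with an estimated correlation). Members also fell in conventional dendritic-like cells (0 over all genes and 16 over the list alone, camera adjusted p = 2.90e-15, adjusted p = 0.426 with an estimated correlation), regulatory T-like cells (2 and 17, camera adjusted p = 2.97e-15, adjusted p = 0.286) and microglia-like cells (0 and 13, camera adjusted p = 5.44e-09, adjusted p = 0.753). Of 20 chemokine genes 3 fell over all genes, and 1 rose and 13 fell over the list alone (camera adjusted p = 7.19e-06, adjusted p = 0.328 with an estimated correlation), including Ccl3 (−0.69) and Cxcl10 (−0.67). The rotation test fry passed for the chemokine list too (adjusted p = 0.0249). In the 20 immunosuppressive myeloid genes 3 fell over all genes, and 1 rose and 6 fell over the list alone (camera adjusted p = 0.0172, adjusted p = 0.453 with an estimated correlation). Interferon gamma genes and MHC class I genes went the other way, with 14 of 23 and 8 of 18 up over the list alone (camera adjusted p = 1.68e-06 and 4.37e-05, adjusted p = 0.651 for both with an estimated correlation). In each comparison no camera call held with an estimated correlation, 0 of 231 in all.

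**Figure D2:**
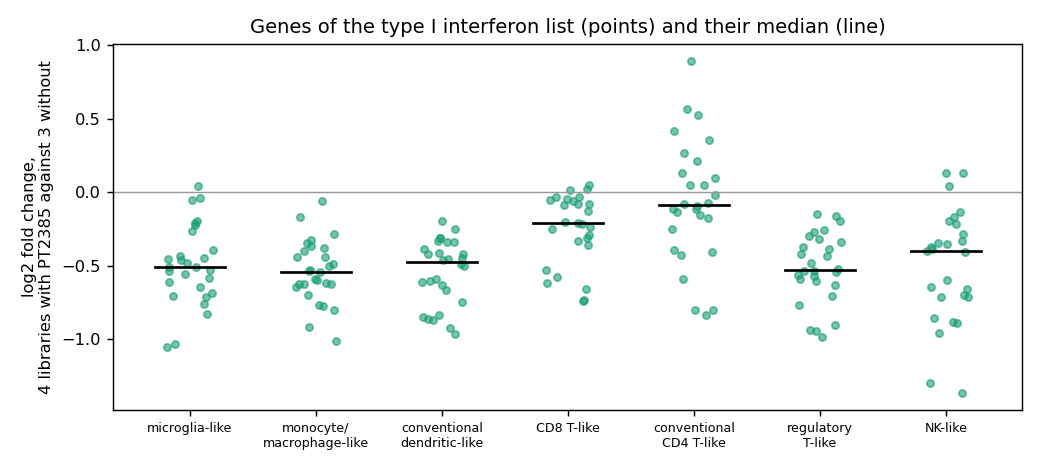
Log2 fold changes of the type I interferon list for the effect of PT2385, by class. Each point is 1 tested member of the list.

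Hypoxia-induced and HIF-2-associated genes did not move as one block with the HIF-2α inhibitor. In monocyte/macrophage-like cells 1 of 31 hypoxia genes rose and 2 fell over the list alone (2 fell over all genes), with a median of 0.24 (camera adjusted p = 0.0172, adjusted p = 0.732 with an estimated correlation). Bhlhe40, a hypoxia- and cytokine-induced repressor, fell by 0.79 (edgeR adjusted p = 0.0176) and the mTOR inhibitor Ddit4 by 0.63 (edgeR adjusted p = 0.0476). The HIF-2-associated list did not pass there (camera adjusted p = 0.702). In microglia-like cells its 13 members had a median of −0.69, with 0 down over all genes and 2 over the list alone (camera adjusted p = 0.00747, adjusted p = 0.531 with an estimated correlation).

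Microglia-like cells changed little with PT2385. 5 of 13787 genes passed and all fell, against 1361 at unadjusted p under 0.05 and 147 by DESeq2. The count was 2 without PT2385 pool 2 and 156 without the untreated library. Antxr2, a collagen-binding receptor, fell by 1.23 ± 0.11 (edgeR adjusted p = 0.0155) and the chemokine receptor Ccr1 by 1.09 ± 0.10 (edgeR adjusted p = 0.0155), and neither passed without PT2385 pool 2 (edgeR adjusted p = 0.109 for both). The protease Napsa fell by 1.11 ± 0.12 in 3 of 4 libraries (edgeR adjusted p = 0.0251) and did not pass in 5 of the 7 fits without 1 library, such as that without combination pool 1 (edgeR adjusted p = 0.162). The other 2, Uck2 (−1.47 ± 0.10, edgeR adjusted p = 0.00321) and Pf4 (−3.30 ± 0.23, edgeR adjusted p = 0.00360), fell outside the naming rule and are given after their values were seen. Both passed in every fit without 1 library. Antxr2 and Uck2 are among the leading genes of the macrophage cluster M0 and Pf4 of the macrophage cluster M5. In cluster M10 alone the 3 that could be tested did not pass, with Antxr2 at −0.23 and Ccr1 and Napsa turned to 0.33 and 1.19. At Leiden resolution 2 0 genes passed in the class, and 0 passed without cluster M17 (edgeR, 930 at unadjusted p under 0.05), a cluster with T cell markers at 24.9% of the T cell level.

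In CD8 T-like cells 12 of 9470 genes passed (1 rose, 11 fell), against 590 at unadjusted p under 0.05 and 20 by DESeq2. Gzmb (granzyme B) fell by 1.03 ± 0.14, from 2361 ± 990 to 1313 ± 606 CPM (edgeR adjusted p = 0.00568), and at −1.09 it did not pass without combination pool 1 (edgeR adjusted p = 0.0808). A cluster of the class led by Gzmf, with Gzmb, Styk1 and Ifitm1 among its leading genes (resolution 2), made up 21.2% of the class in the untreated library and 0.488 to 6.54% in the others. Without it Gzmb lay at −0.67 and Styk1 at −0.92 (edgeR adjusted p = 0.0338 and 0.0352). The kinase-like gene Styk1 fell by 1.24 ± 0.16 (edgeR adjusted p = 0.00207) and the survival gene Bcl2l1 by 1.17 ± 0.17 (edgeR adjusted p = 0.00509), each in every fit without 1 library. Cd200r1 rose by 1.2 ± 0.18 (edgeR adjusted p = 0.00694) but not without the untreated library (1.11, edgeR adjusted p = 0.0714). The count of genes was 47 without combination pool 2 and 7 without PT2385 pool 1.

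In NK-like cells 117 of 9934 genes passed (18 rose, 99 fell), against 1083 at unadjusted p under 0.05 and 91 by DESeq2. Without the untreated library 17 passed. Cd200r1 rose by 1.45 ± 0.21, from 22.1 ± 8.71 to 55.3 ± 10.6 CPM (edgeR adjusted p = 5.77e-04). The residency receptor Cxcr6 rose by 1.04 (edgeR adjusted p = 0.00334), and without the untreated library by 0.75 (edgeR adjusted p = 0.128). The adhesion molecule Alcam fell by 1.14 (edgeR adjusted p = 0.00334) and the semaphorin receptor Plxnc1 by 1.15 ± 0.16 (edgeR adjusted p = 5.77e-04, 0.0543 without the untreated library). Cd200r1 and Alcam passed in every fit without 1 library. The stem or memory list fell in NK-like cells, with 1 of 12 members over all genes (Bach2) and 6 over the list alone (camera adjusted p = 1.73e-04, adjusted p = 0.243 with an estimated correlation). Of 18 dissociation-stress genes, which handling of the tissue can raise, 3 fell over all genes, Jund among them, and 7 over the list alone (camera adjusted p = 9.05e-04, adjusted p = 0.243).

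In conventional CD4 T-like cells 18 of 10221 genes passed (6 rose, 12 fell), against 1011 at unadjusted p under 0.05 and 50 by DESeq2. Gzmf, a granzyme, had 2 UMIs in 4 libraries with PT2385 and 332 in 3 without, a ratio of 0.00470 (exact 95% interval of counting alone 5.67e-04 to 0.0171, edgeR adjusted p = 9.68e-08). 329 of the 332 came from the untreated library, so the spread between libraries is wider than that interval. Il2, the T cell growth factor, fell by 2.79 ± 0.44 (edgeR adjusted p = 0.0377), and without PT2385 pool 2 by 2.78 (edgeR adjusted p = 0.0849). Of 19 proliferation genes 0 fell over all genes and 4 over the list alone (camera adjusted p = 8.36e-08, adjusted p = 0.301 with an estimated correlation). Without PT2385 pool 1 the count was 4.

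Activation transcripts were lower in the summed regulatory T-like profiles with PT2385. 43 of 11315 genes passed (20 rose, 23 fell), against 1016 at unadjusted p under 0.05 and 65 by DESeq2, and 15 without combination pool 1. Of 19 regulatory T activation genes 7 fell over all genes and 10 over the list alone (camera adjusted p = 1.13e-09, adjusted p = 0.286 with an estimated correlation, fry adjusted p = 0.0389). They include the costimulatory receptors Tnfrsf4 (−0.66) and Tnfrsf18 (−0.57), the IL-2 receptor gene Il2ra (−0.53) and Ctla4 (−0.44). Nos2 rose by 4.91 ± 0.34 (edgeR adjusted p = 9.83e-05). Cluster T15, 25.2 to 34.6% of the cells of the class, held 531 of the 534 Nos2 UMIs, and its macrophage markers stood at 51.6% of the macrophage level. T15 made up 26.4 to 34.6% of the cells in libraries with PT2385 and 25.2 to 27.2% in those without. Its weight in the summed counts is larger, since its cells held 2.11 times the median UMIs of their libraries. Those of T1, most of the class, held 0.733 times. The activation list was not tested without T15 in any comparison. Its fall therefore cannot be told apart from the weight of T15 in the sums. Without T15 22 genes passed. Gzmb fell by 1.10 ± 0.16 in the class (edgeR adjusted p = 0.0369, 0.150 without the untreated library) and by 1.05 without T15 (edgeR adjusted p = 2.49e-07). The non-coding Gm17767 fell by 1.54 ± 0.19 (edgeR adjusted p = 0.00672), by 1.45 without T15 (edgeR adjusted p = 0.00206), and in every fit without 1 library.

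In conventional dendritic-like cells 3 of 11435 genes passed, against 899 at unadjusted p under 0.05 and 45 by DESeq2. Saa3, an acute-phase gene of macrophages (4.01 ± 0.50), and the guanylate-binding protein gene Gbp2b (1.97) rose, and the lipocalin Apod fell by 2.44 (edgeR adjusted p = 0.0237 for each). The 3 lie outside the naming rule and were chosen after their values were seen. None passed without PT2385 pool 1, where they lay at 4.12, 2.01 and −2.31 (edgeR adjusted p = 0.0597, 0.0597 and 0.136). Cluster M15 matches the marker list of type 1 conventional dendritic cells (cDC1), with Xcr1, Clec9a and Itgae among its leading genes. It was left out for its depth, 2.33 times the median UMIs of its libraries. Its macrophage markers stood at 9.7% of the macrophage level, against 23.6% in cluster M4 of the class, which was kept. Without cluster M15 Saa3 and Gbp2b lay at 3.23 and 0.89 without passing (edgeR adjusted p = 0.215 and 0.703).

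With ICB more genes passed in microglia-like cells than in any other class. The mix of clusters within that class differed too. Gzmb fell in CD8 T-like and conventional CD4 T-like cells. Without the untreated library it lay at −1.03 and −1.41 there without passing (edgeR adjusted p = 0.0967 and 0.127). Of 22 named gene results 9 rose and 13 fell, and 4 passed in every fit without 1 library.

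In microglia-like cells 1768 of 13787 genes passed with ICB (679 rose, 1089 fell), against 4485 at unadjusted p under 0.05 and 2230 by DESeq2. Without combination pool 2 the count was 89, and without ICB pool 2 it was 2695. At Leiden resolution 2 it was 220. All 28 type I interferon genes fell over the list alone and 23 over all genes (camera adjusted p = 3.95e-14, adjusted p = 0.531 with an estimated correlation), with the regulator Irf7 at −1.65 and Oas3 at −1.45. MHC class II genes fell, 8 of 9 over all genes and 9 over the list alone (camera adjusted p = 6.31e-07, adjusted p = 0.531 with an estimated correlation), as did MHC class I genes (9 of 18 and 15, camera adjusted p = 2.58e-07, adjusted p = 0.531) and interferon gamma genes (14 of 22 and 19, camera adjusted p = 1.35e-10, adjusted p = 0.531). Il1b (−1.85) and the costimulatory Cd40 (−2.12) fell. Of 16 homeostatic microglia genes 3 rose over all genes and 9 over the list alone (camera adjusted p = 1.80e-05, adjusted p = 0.531 with an estimated correlation), including P2ry13 (0.87) and Siglech (0.77). 4 of 31 hypoxia genes fell over all genes, and 2 rose and 15 fell over the list alone (camera adjusted p = 0.00315, adjusted p = 0.598). The HIF subunit genes Hif1a (−0.87 ± 0.21) and Arnt (−0.31 ± 0.08) fell (edgeR adjusted p = 0.0388 for both), and of the 7 fits without 1 library Hif1a lost its call in 5 and Arnt in 6, for example without combination pool 2 (−0.72 and −0.33, edgeR adjusted p = 0.129 and 0.130).

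The largest falls by the naming rule were Nos2 (−4.01 ± 0.87, edgeR adjusted p = 0.0425), the growth factor Nrg1 (−3.03, edgeR adjusted p = 0.0358) and the orphan receptor Gpr141 (−2.96 ± 0.34, edgeR adjusted p = 0.0129). Without combination pool 2 they lay at −3.67, −2.62 and −2.75 (edgeR adjusted p = 0.194, 0.135 and 0.0574). Ttr rose by 3.84 ± 0.64 (edgeR adjusted p = 0.0262, 0.113 without combination pool 2), and the immunoglobulin gene Igkc by 2.21 ± 0.23 in every fit without 1 library (edgeR adjusted p = 0.0101). These are genes of choroid plexus and B cells. Cluster M10 made up 72.1% and 49.3% of the class in the ICB pools and 60.2% and 80.6% in the combination pools, against 45.0% in the untreated library. Cluster M14, with Cxcl13, C4b and Il1a and macrophage markers at 43.3% of the macrophage level, went from 37.6% in the untreated library to 16.3% and 33.8% with ICB and 13.4% and 9.0% with both. Within M10 alone 52 genes passed (50 rose, 2 fell). Nrg1 and Gpr141 turned there to 0.56 and 1.54 without passing. There Ttr rose by 7.16 (edgeR adjusted p = 5.02e-11) and the signalling gene Pik3r3 by 1.36 (edgeR adjusted p = 0.00280).

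**Figure D3:**
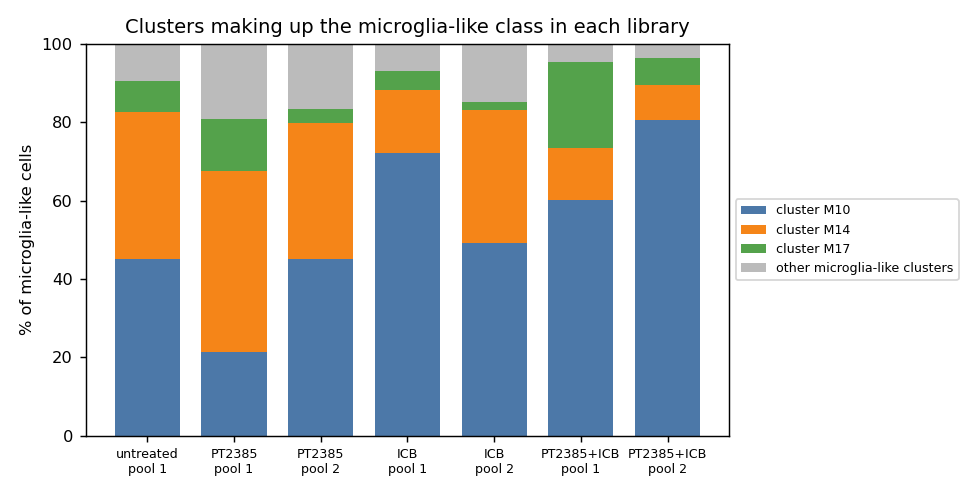
Share of the microglia-like class in each of its clusters, by library.

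No gene passed for ICB in monocyte/macrophage-like cells (edgeR), against 1538 at unadjusted p under 0.05 and 117 by DESeq2. Without ICB pool 1 31 genes passed. Of its type I interferon genes 0 passed by either adjustment, while camera placed the list lower (camera adjusted p = 1.66e-04, adjusted p = 0.703 with an estimated correlation). Cluster M5 (Ccl24, Mrc1, Pf4) made up 46.4% of this class in ICB pool 1 and at most 2.7% in each other library. The smallest p belonged to Igfbp2, at 3.8 without passing (edgeR adjusted p = 0.198).

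In CD8 T-like cells 6 genes passed (2 rose, 4 fell), against 429 at unadjusted p under 0.05 and 10 by DESeq2. Gzmb fell by 1.00 ± 0.14, from 2339 ± 1067 to 1329 ± 554 CPM (edgeR adjusted p = 0.0105), and Styk1 by 1.25 ± 0.16 (edgeR adjusted p = 0.00191). Without the untreated library these stood at −1.03 and −1.14 (edgeR adjusted p = 0.0967 for both), and without the Gzmf-led cluster at −0.81 and −1.09 (edgeR adjusted p = 0.00485 and 0.00678). The MHC class II genes H2-Ab1 (−0.83) and H2-Eb1 (−0.85) fell (edgeR adjusted p = 0.0360 and 0.0397). Neither passed without the untreated library (edgeR adjusted p = 0.414 and 0.397), and at Leiden resolution 2 they lay at −0.08 and 0.12. Ttr rose by 6.81 ± 0.41 (edgeR adjusted p = 1.86e-04). The sixth gene, the peptide transporter Slc15a2 (2.02, edgeR adjusted p = 0.0262), was chosen after its value was seen. 1 of 20 cytotoxic genes fell over all genes and 2 over the list alone (camera adjusted p = 0.00108, adjusted p = 0.171 with an estimated correlation).

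**Figure D4:**
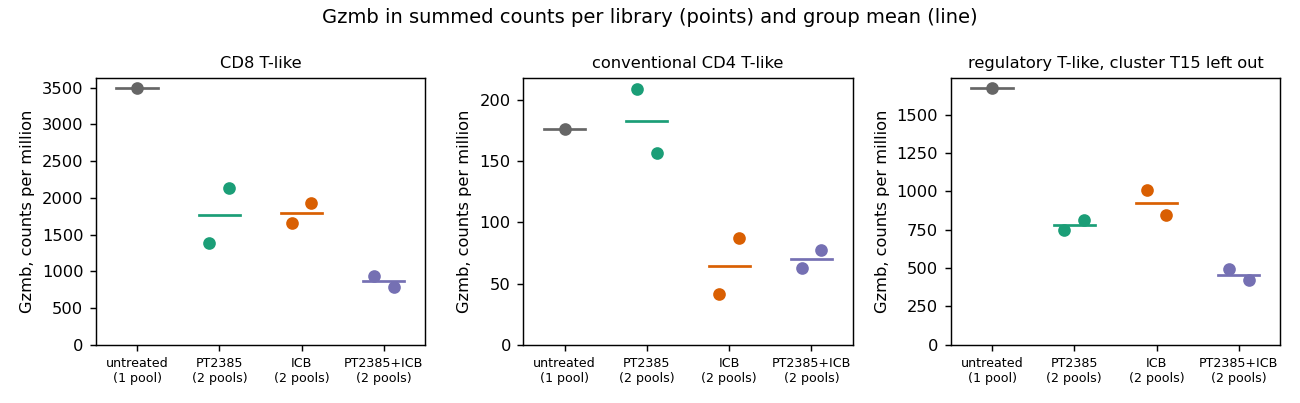
Gzmb in CD8 T-like cells, CPM in each library.

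In conventional CD4 T-like cells 10 genes passed (1 rose, 9 fell), against 814 at unadjusted p under 0.05 and 36 by DESeq2, and 27 without combination pool 1. Of 20 cytotoxic genes 3 fell over all genes and 4 over the list alone (camera adjusted p = 7.10e-07, adjusted p = 0.0836 with an estimated correlation). Gzmf had 3 UMIs with ICB and 331 without (ratio 0.00889, exact 95% interval of counting alone 0.00182 to 0.0262, edgeR adjusted p = 2.54e-07). The untreated library held 329 of the 331, which leaves 2 without ICB, and with DESeq2 Gzmf did not pass (−4.89, adjusted p = 0.774). Prf1 (perforin) fell by 1.08 (edgeR adjusted p = 0.00787) and Gzmb by 1.42 ± 0.21 (edgeR adjusted p = 0.0343, 0.127 at −1.41 without the untreated library). The protease inhibitor Serpine2 fell by 2.02 ± 0.25 (edgeR adjusted p = 0.00298, 0.0502 without the untreated library).

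In regulatory T-like cells 5 genes passed with ICB, all up, against 795 at unadjusted p under 0.05 and 19 by DESeq2. The membrane protein gene Tmem176a rose by 1.33 ± 0.14 (edgeR adjusted p = 0.00203), but not without cluster T15 (0.99, edgeR adjusted p = 0.412). The iron transporter Slc11a1 rose by 0.92 (edgeR adjusted p = 0.0377, 0.0699 without combination pool 2). Chosen after their values were seen, the B cell scaffold gene Bank1 (3.54, edgeR adjusted p = 0.0282), the lipid receptor Pparg (1.76) and Rnf150 (1.83, edgeR adjusted p = 0.0377 for both) complete the 5. Of the 5 only Tmem176a and Pparg could be tested without T15, and Pparg did not pass either (1.67, edgeR adjusted p = 0.173). 1 gene passed in NK-like cells, Cmss1, a ribosome-assembly gene (0.60 ± 0.09, edgeR adjusted p = 0.00726, 0.0869 without PT2385 pool 1). In conventional dendritic-like cells only the diacylglycerol kinase Dgkh passed (−1.08 ± 0.13, edgeR adjusted p = 0.0257, 0.255 without the untreated library). The unadjusted and DESeq2 counts were 480 and 4 in NK-like cells and 894 and 12 in dendritic-like cells.

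Between the combination and ICB, Dab2, which leads a macrophage cluster, fell in microglia-like cells. Csf2 and Il2 fell in conventional CD4 T-like cells. The microglia-like share was 12.4% with ICB and 29.6% with both. Of 45 named gene results 22 rose and 23 fell, and 6 passed in every fit without 1 library.

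In microglia-like cells 156 genes passed between the combination and ICB (10 rose, 146 fell), against 2365 at unadjusted p under 0.05 and 480 by DESeq2. The count was 12 without combination pool 2, 251 without ICB pool 1, 14 in cluster M10 alone and 0 at Leiden resolution 2. Dab2, an endocytic adaptor, fell by 2.30 ± 0.11, from 99.9 ± 1.69 to 20.3 ± 0.375 CPM (edgeR adjusted p = 7.29e-04), and passed in every fit without 1 library. The scavenger receptor Msr1 fell by 2.25 (edgeR adjusted p = 0.0141) and the macrophage gene Ms4a7 by 2.54 ± 0.25 (edgeR adjusted p = 0.0161), which without ICB pool 2 lay at −2.08 and −2.28 (edgeR adjusted p = 0.0976 and 0.0753). Dab2 leads the macrophage cluster M0 and Ms4a7 is a leading gene of M2. Cluster M14, with macrophage markers at 43.3% of the macrophage level, made up 16.3% and 33.8% of the class with ICB and 13.4% and 9.0% with both. Type I interferon genes fell, 6 over all genes and 20 over the list alone (camera adjusted p = 2.63e-12, adjusted p = 0.453 with an estimated correlation). Of 20 proliferation genes 3 fell over all genes and 12 over the list alone (camera adjusted p = 2.53e-10, adjusted p = 0.299), such as Mcm5 (−1.73) and Stmn1 (−1.18). Chemokine genes fell as well (3 of 18 over all genes, 11 over the list alone, camera adjusted p = 7.47e-09, adjusted p = 0.299), and so did HIF-2-associated genes (3 of 13 and 5, camera adjusted p = 0.00724, adjusted p = 0.299), among them Mmp14 (−1.16) and Ccnd1 (−0.87). Gzmk, a T cell granzyme, rose by 8.74 (edgeR adjusted p = 0.0147), and cluster M17 made up 21.8% and 6.9% of this class with both treatments and 4.7% and 2.1% with ICB. In monocyte/macrophage-like cells 0 genes passed (edgeR), against 1875 at unadjusted p under 0.05 and 228 by DESeq2, but 1583 passed without ICB pool 2.

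In conventional CD4 T-like cells 21 genes passed (7 rose, 14 fell), against 1357 at unadjusted p under 0.05 and 23 by DESeq2. Csf2 (GM-CSF) fell by 3.23 ± 0.34, from 244 ± 55.9 to 29.1 ± 15.6 CPM (edgeR adjusted p = 0.0184), in every fit without 1 library. Il2 fell by 3.21 ± 0.46 (edgeR adjusted p = 0.0224, 0.0546 without PT2385 pool 1) and the galectin Lgals7 by 2.45 (edgeR adjusted p = 0.0216, 0.351 without combination pool 1). Of 19 proliferation genes 1 fell over all genes and 10 over the list alone (camera adjusted p = 5.04e-08, adjusted p = 0.561 with an estimated correlation). C1qc, a complement gene of microglia and macrophages, rose by 1.64 (edgeR adjusted p = 0.0339, 0.177 without ICB pool 2 and 0.309 without combination pool 1). Without combination pool 2 322 genes passed and without PT2385 pool 1 3.

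In CD8 T-like cells 17 genes passed (5 rose, 12 fell), against 613 at unadjusted p under 0.05 and 9 by DESeq2. Bcl2l1 fell by 1.28 (edgeR adjusted p = 0.0207) and Gzmb, named here after its value was seen, by 1.06 ± 0.18, from 1795 ± 196 to 863 ± 109 CPM (edgeR adjusted p = 0.0347). Without combination pool 2 they lay at −0.94 and −0.94 (edgeR adjusted p = 0.0791 and 0.141), and neither passed without the Gzmf-led cluster (edgeR adjusted p = 0.0744 and 0.0516). 1 of 12 stem or memory genes fell over all genes, the chromatin organizer Satb1, and 7 over the list alone (camera adjusted p = 3.64e-07, adjusted p = 0.777 with an estimated correlation). Ttr (1.64 ± 0.25) and the complement gene C1qb (1.2) rose (edgeR adjusted p = 0.0207 for both), and neither passed without PT2385 pool 1 (edgeR adjusted p = 0.0731 and 0.0968). At Leiden resolution 2 C1qb turned to −1.55. Without combination pool 1 120 genes passed and without PT2385 pool 1 2.

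In regulatory T-like cells 46 genes passed (36 rose, 10 fell), against 1002 at unadjusted p under 0.05 and 52 by DESeq2, and 114 without ICB pool 2. Nos2 had 155 UMIs with both treatments and 2 with ICB (ratio 77.5, exact 95% interval 21.1 to 645, edgeR adjusted p = 5.07e-04). Gzma (granzyme A) rose by 3.53 ± 0.29 (edgeR adjusted p = 0.00968), and without cluster T15 stood at 3.92 without passing (edgeR adjusted p = 0.202). 4 of 9 MHC class II genes rose over all genes and 8 over the list alone (camera adjusted p = 1.29e-07, adjusted p = 0.521 with an estimated correlation). Cluster T15 made up 34.6% and 33.3% of the class with both treatments and 25.2% and 27.2% with ICB. Without it 19 genes passed, and with doublets kept 0. 4 of 19 activation genes fell over all genes and 9 over the list alone (camera adjusted p = 8.95e-07, adjusted p = 0.521). Gm17767 fell by 1.73 (edgeR adjusted p = 0.00976, 0.0516 without combination pool 1).

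In NK-like cells 33 genes passed (10 rose, 23 fell), against 865 at unadjusted p under 0.05 and 8 by DESeq2, and 11 without combination pool 2. The histone gene Hist1h2ae fell by 2.94 ± 0.40, from 39.6 ± 0.778 to 5.11 ± 2.51 CPM (edgeR adjusted p = 2.78e-04), in every fit without 1 library. The maturation receptor Klrg1 rose by 2.09 ± 0.32 (edgeR adjusted p = 0.00518, 0.0919 without combination pool 2), Cd200r1 by 1.38 (edgeR adjusted p = 0.0146, 0.180 without ICB pool 1) and the fractalkine receptor Cx3cr1 by 1.35 (edgeR adjusted p = 0.0415, 0.529 without ICB pool 1). In conventional dendritic-like cells 5 genes passed, against 909 at unadjusted p under 0.05 and 22 by DESeq2, and 0 without combination pool 2. The sterol hydroxylase Cyp7b1 (−3.12 ± 0.33) and the lectin Mgl2 (−1.75) fell (edgeR adjusted p = 0.00930 for both, 0.205 for both without combination pool 2) and passed without cluster M15 too. The sterol regulator Insig1 fell by 1.64 (edgeR adjusted p = 0.0337). The macrophage genes Apoe (1.52 ± 0.12, edgeR adjusted p = 9.04e-04) and Trem2 (1.55, edgeR adjusted p = 0.0439) rose. They lay at −0.98 and −0.08 without M15, the cDC1 cluster.

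Set against the untreated library, the combination had lower Htr7 in microglia-like cells and lower Gzmb in CD8 T-like cells. These comparisons rest on 1 reference library. No fit could leave it out, so passing in every fit without 1 library does not test that library. Of 37 named gene results 17 rose and 20 fell, and 13 passed in every fit without 1 library.

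In microglia-like cells 789 genes passed (113 rose, 676 fell), against 3351 at unadjusted p under 0.05 and 966 by DESeq2, 143 without combination pool 2 and 7 at Leiden resolution 2. Htr7, a serotonin receptor, fell by 4.04 ± 0.25 (edgeR adjusted p = 6.30e-04) and the phosphodiesterase Pde7b by 3.58 (edgeR adjusted p = 0.00125), each in every fit without 1 library. Within cluster M10 Pde7b lay at 0.70 without passing (edgeR adjusted p = 0.839). 19 of 28 type I interferon genes fell over all genes and 24 over the list alone (camera adjusted p = 1.07e-14, adjusted p = 0.552 with an estimated correlation, fry adjusted p = 0.0394), Irf7 by 2.49. 7 of 9 MHC class II genes fell by either adjustment (camera adjusted p = 5.84e-06, adjusted p = 0.561), and so did 4 of 13 HIF-2-associated genes over all genes and 6 over the list alone (camera adjusted p = 0.0179, adjusted p = 0.552, fry adjusted p = 0.0379), such as Cxcr4 (−2.50), Flt1 (−2.46) and Plin2 (−1.75). Ttr had 9641 UMIs against 1 (ratio 1392, exact 95% interval 249.8 to 54990, edgeR adjusted p = 0.0149), and 0.0687 without combination pool 1. No gene passed in monocyte/macrophage-like cells (edgeR), against 1749 at unadjusted p under 0.05, 194 by DESeq2 and 353 without ICB pool 1. Type I interferon genes there fell in 0 cases over all genes and 22 over the list alone (camera adjusted p = 1.07e-13, adjusted p = 0.387).

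In CD8 T-like cells 17 genes passed (3 rose, 14 fell), against 577 at unadjusted p under 0.05 and 14 by DESeq2, and 88 without combination pool 1. Gzmb fell by 2.02 ± 0.21, from 3492 to 863 ± 109 CPM (edgeR adjusted p = 2.88e-04), Styk1 by 2.50 ± 0.24 (edgeR adjusted p = 1.02e-05), the interferon-induced Ifitm1 by 2.09 ± 0.16 (edgeR adjusted p = 1.08e-07) and Csf1 by 1.88 (edgeR adjusted p = 0.00137), all in every fit without 1 library. Cd200r1 rose by 1.70 (edgeR adjusted p = 0.00869, 0.0536 without PT2385 pool 1). Without the Gzmf-led cluster 4 genes passed, Gzmb (−1.44, edgeR adjusted p = 2.73e-04), Styk1, Ifitm1 (−1.15) and Ttr, and Csf1 and Cd200r1 did not (edgeR adjusted p = 0.290 and 0.0978). Ttr had 824 UMIs against 0, at least 226-fold more (edgeR adjusted p = 1.02e-05). In conventional CD4 T-like cells 11 genes passed (1 rose, 10 fell), against 852 at unadjusted p under 0.05 and 11 by DESeq2, and 116 without combination pool 2. Gzmf had 0 UMIs against 329, at least 152-fold fewer (edgeR adjusted p = 1.48e-05). The unconventional myosin gene Myo10 fell by 1.92 (edgeR adjusted p = 0.0214, 0.185 without combination pool 1).

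In regulatory T-like cells 26 genes passed (13 rose, 13 fell), against 915 at unadjusted p under 0.05 and 29 by DESeq2, and 11 without combination pool 2. 3 of 19 activation genes fell over all genes and 10 over the list alone (camera adjusted p = 8.27e-10, adjusted p = 0.318 with an estimated correlation), including Tnfrsf4 (−1.01), Tnfrsf18 (−0.81) and the cytokine Il10 (−1.06). Gzmb, which did not pass in the whole class, fell by 1.87 without cluster T15 (edgeR adjusted p = 3.08e-09). In NK-like cells 27 genes passed (5 rose, 22 fell), against 820 at unadjusted p under 0.05 and 9 by DESeq2, and 7 without combination pool 1. Alcam fell by 1.74 (edgeR adjusted p = 0.0163, 0.142 without combination pool 1) and Cd200r1 rose by 1.95 (edgeR adjusted p = 0.0170, 0.113 without combination pool 1). Apoe alone passed in conventional dendritic-like cells (1.36, edgeR adjusted p = 0.0342, 767 at unadjusted p under 0.05, 12 by DESeq2), and lay at −0.57 without cluster M15.

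The contrast of the PT2385 effect with and without ICB, which rests on the lone untreated library, passed for few genes. 0 passed in microglia-like (edgeR, 1700 at unadjusted p under 0.05, 134 by DESeq2), monocyte/macrophage-like (592 and 6) and conventional CD4 T-like cells (741 and 0). The interaction passed for 4 genes in CD8 T-like, 6 in regulatory T-like, 2 in NK-like cells and 1 in conventional dendritic-like cells. The microglia-like share showed no interaction (0.46 ± 0.58, edgeR adjusted p = 0.698). The following were chosen after their values were seen. In CD8 T-like cells the 4 were Ifitm1 (1.97, edgeR adjusted p = 7.19e-05), 1700025G04Rik (−2.79), Igkc (2.62) and the interferon-induced GTPase Iigp1 (−2.62), of which only Igkc passed without the Gzmf-led cluster (edgeR adjusted p = 0.0363). In NK-like cells they were Hist1h2ae (−3.63, edgeR adjusted p = 0.00430) and the lymphotoxin gene Lta (−4.05, edgeR adjusted p = 0.0139), and in conventional dendritic-like cells Apoe (1.88, edgeR adjusted p = 0.00796). The regulatory T-like genes were Gzma, Vegfa, Cd14, Ern1, Apoe and Klra4 (edgeR adjusted p = 0.0299 for each), mostly genes of myeloid or NK cells. None of the 6 passed with doublets kept.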

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

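The tests of other splits, of Ttr in dendritic-like cells, of Nos2 in cluster T15 and of fits without single clusters or of M10 alone were chosen after the result was seen.

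The contrast of the PT2385 effect with and without ICB passed for 13 gene results, given as the log2 effect with ICB minus that without. It rests on the lone untreated library, which no fit without 1 library could leave out. In CD8 T-like cells these were Ifitm1 (1.97), 1700025G04Rik (−2.79), the B cell gene Igkc (2.62) and Iigp1 (−2.62). Ifitm1 passed in every fit without 1 library, at 1.87 to 2.06, but lay at 1.26 without the Gzmf-led cluster (edgeR adjusted p = 0.108). In regulatory T-like cells they were Gzma (5.72), Vegfa (1.72), Cd14 (1.38), Ern1 (1.31), Apoe (1.33) and Klra4 (7.04). Cd14 and Apoe are myeloid genes, and Gzma and Klra4 are NK cell genes. With doublets kept none of the 6 passed and Klra4 turned to −0.48. Without cluster T15, whose cells carry macrophage markers, Gzma stood at 6.70 and Apoe at 0.95 without passing, so the class there may hold more than 1 cell type. In NK-like cells Hist1h2ae (−3.63) and Lta (−4.05) differed, and neither passed without PT2385 pool 2 (−3.27 and −3.94). In conventional dendritic-like cells Apoe differed by 1.88, and by −1.10 without cluster M15. Sorting regulatory T and dendritic cells by 2 surface markers each and measuring Apoe and Gzma would tell whether those cells make the transcripts.

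Cells led by choroid plexus genes, which a CD45 gate should exclude, averaged 0.280% of retained cells with PT2385, 2.57% with ICB and 11.1% with both. Cells led by ependymal genes averaged 0.223 ± 0.285% with both, with 1 cell in pool 1 and 22 in pool 2. Ttr, the main choroid plexus transcript, was also found in leukocyte classes of the libraries with ICB. If free RNA carried it there, other choroid plexus genes should follow in their proportion to Ttr. Over 35 combinations of gene, class and library in the 2 combination pools their median log2 deviation from that proportion was −0.28, within the range free RNA predicts. Combinations with few UMIs were left out, which can raise that median. If doublets carried it, few cells should hold most of it. The 1% of cells with most Ttr held 7.93% of its UMIs in the median over classes and libraries and at most 19.9% outside dendritic-like cells, which argues against doublets there. In dendritic-like cells 2 of 119 cells held 48.1% and 65.4% in the 2 combination pools. Ttr per UMI differed 2.44-fold between the highest class, dendritic-like cells, and the lowest in the library where it varied less. Those 2 cells raise that value. In the 6 other classes Ttr stood at 217 to 287 CPM in combination pool 1 and at 223 to 285 CPM in pool 2. Such similar levels in unlike cells argue against transcription by the cells of these 6 classes, while it stays open in dendritic-like cells. Without the 1% of cells with most Ttr, dendritic-like cells stood at 284 CPM against 267 in the highest other class in pool 1. In pool 2 they stood at 457 against 268, a ratio of 1.70, which leaves doublets there open. The rise of Ttr in leukocytes may therefore follow from the number of choroid plexus cells in the suspension. Dissecting the ventricles from the tumour before dissociation, or removing free RNA with the empty droplets, would test this.

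The lower transcripts in microglia-like cells with ICB have 2 candidate sources besides a change within cells. Of the 1089 genes that fell, 6.61% were no higher in monocyte/macrophage-like than in microglia-like cells of the mice without ICB, which leaves RNA carried over from macrophages possible. Within cluster M10 alone the median change of the fallen genes was 23% of that in the whole class, −0.15 against −0.66. Another mix of microglia-like clusters could thus account for much of the fall, and 688 of 901 fallen genes testable in M10 were still below 0 there. Staining for a marker of M14 such as Cxcl13 beside P2RY12 would show whether M14 cells are microglia.

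Nos2 appeared in regulatory T-like cells with PT2385. Its level was 68.0 times that of the other lymphoid classes, which free RNA from macrophages cannot give. Cells with a Nos2 UMI had 1.47 times the macrophage-marker share of cells without in the median (1.15 to 2.16 over the 4 libraries), short of the 2 times in every library asked of doublets. They also held more UMIs, a median of 20973 to 36533 against 8944.5 to 11553, as doublets would, although cells with more UMIs show any transcript more often. In cluster T15 Nos2 stood, as percent of its macrophage level, at 1.43 times the percent of other macrophage genes. This last value lies in the range that doublets gathered in 1 cluster would give, but the macrophage-marker share does not decide. Without PT2385, macrophage genes of T15 also stood at 33.5% of their macrophage level in the untreated library and 62.1% and 32.4% with ICB. Cluster T1, most of the class, held at most 1 Nos2 UMI in each library with PT2385, which argues against transcription by T1 cells. Cells of T15 held 2.11 times the median UMIs of their libraries. T cell markers there stood at 43.1% of the T cell level, against 91.1% in T1, and macrophage markers at 51.6% of theirs. Doublets would give such a mix at such depth. Transcription of Nos2 by regulatory T cells of T15 is not excluded by these values. Imaging or indexed sorting of FOXP3-positive, CD11b-positive events would tell doublets from single cells.

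The 7 libraries were also split in other ways into 4 and 3, each split counting genes as the real one does. Of 34 splits that can be fitted, the numbers that gave as many genes as the real one, the real one included, follow with the real count and the highest other. With PT2385 only the real split gave as many genes in microglia-like (1, real 5, highest other 3), regulatory T-like (1, real 43, highest other 5) and NK-like cells (1, real 117, highest other 8). This 1 of 34, the smallest share the design allows, lies under 0.05 for a single count. It is not adjusted over the 14 counts, so chance is not excluded. The margin is small in microglia-like cells, where 0 genes passed without cluster M17 or at Leiden resolution 2. Other splits gave as many genes in monocyte/macrophage-like (2, real 125, highest other 186), conventional dendritic-like (3, real 3, highest other 11), CD8 T-like (4, real 12, highest other 28) and conventional CD4 T-like cells (2, real 18, highest other 109). For ICB chance cannot be excluded in the 6 classes with a gene, and in monocyte/macrophage-like cells a real count of 0 leaves nothing to test. The values are microglia-like 2, real 1768, highest other 1784, monocyte/macrophage-like 34, real 0, highest other 14, conventional dendritic-like 14, real 1, highest other 42, CD8 T-like 5, real 6, highest other 41, conventional CD4 T-like 3, real 10, highest other 86, regulatory T-like 3, real 5, highest other 47, and NK-like cells 20, real 1, highest other 11. Splits that call more than 3 times the real count, as in conventional dendritic-like and conventional CD4 T-like cells with PT2385 and in all 6 classes besides microglia-like cells with ICB, point to other structure among the samples.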

How the results depend on the processing

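The settings were fixed before the data were examined, except those on single clusters, on unnamed clusters, on the doublet rate and on the classes with a mean of at least 10 cells, which were chosen after results were seen. Counts are of genes with edgeR adjusted p under 0.05, and a count is listed where it moved more than 1.5-fold. Class names are shortened, so that microglia stands for microglia-like cells. In each case the cause was not tested. No paired analysis was possible because the replicate numbers give the order of the records and not shared mice or batches.

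With DESeq2 in place of edgeR gene counts moved for PT2385 from 5 to 147 in microglia, 125 to 1054 in macrophages, 3 to 45 in dendritic cells, 12 to 20 in CD8 T cells, 18 to 50 in CD4 T cells and 43 to 65 in regulatory T cells. For ICB they moved from 0 to 117 in macrophages, 1 to 12 in dendritic cells, 6 to 10 in CD8 T cells, 10 to 36 in CD4 T cells, 5 to 19 in regulatory T cells and 1 to 4 in NK cells. For both against ICB they moved from 156 to 480 in microglia, 0 to 228 in macrophages, 5 to 22 in dendritic cells, 17 to 9 in CD8 T cells and 33 to 8 in NK cells. For both against none they moved from 0 to 194 in macrophages, 1 to 12 in dendritic cells and 27 to 9 in NK cells. For the interaction they moved from 0 to 134 in microglia, 0 to 6 in macrophages, 1 to 2 in dendritic cells, 4 to 1 in CD8 T cells and 2 to 0 in NK cells.

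With no filter on low counts gene counts moved for PT2385 from 5 to 40 in microglia, 125 to 486 in macrophages, 3 to 233 in dendritic cells, 12 to 86 in CD8 T cells, 18 to 272 in CD4 T cells, 43 to 310 in regulatory T cells and 117 to 296 in NK cells. The counts for ICB went from 0 to 32 in macrophages, 1 to 204 in dendritic cells, 6 to 42 in CD8 T cells, 10 to 166 in CD4 T cells, 5 to 179 in regulatory T cells and 1 to 33 in NK cells. The counts for both against ICB went from 156 to 577 in microglia, 0 to 46 in macrophages, 5 to 237 in dendritic cells, 17 to 102 in CD8 T cells, 21 to 346 in CD4 T cells, 46 to 291 in regulatory T cells and 33 to 136 in NK cells. The counts for both against none went from 789 to 1399 in microglia, 0 to 110 in macrophages, 1 to 171 in dendritic cells, 17 to 91 in CD8 T cells, 11 to 191 in CD4 T cells, 26 to 239 in regulatory T cells and 27 to 106 in NK cells. The counts for the interaction went from 0 to 201 in microglia, 0 to 2 in macrophages, 1 to 55 in dendritic cells, 4 to 61 in CD8 T cells, 0 to 86 in CD4 T cells, 6 to 86 in regulatory T cells and 2 to 25 in NK cells.

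With doublets kept gene counts moved for PT2385 from 5 to 9 in microglia, 3 to 178 in dendritic cells and 117 to 230 in NK cells. ICB gave shifts from 1768 to 2927 in microglia, 1 to 219 in dendritic cells, 5 to 3 in regulatory T cells and 1 to 12 in NK cells. Both against ICB gave shifts from 5 to 713 in dendritic cells, 46 to 0 in regulatory T cells and 33 to 86 in NK cells. Both against none gave shifts from 789 to 1813 in microglia, 1 to 413 in dendritic cells, 26 to 1 in regulatory T cells and 27 to 76 in NK cells. The interaction gave shifts from 1 to 25 in dendritic cells, 6 to 0 in regulatory T cells and 2 to 0 in NK cells. The sign turned for Klra4 in regulatory T cells for the interaction (from 7.04 to −0.48).

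With finer clusters (Leiden resolution 2) gene counts moved for PT2385 from 5 to 0 in microglia and 3 to 1 in dendritic cells. Counts moved for ICB from 1768 to 220 in microglia, 1 to 0 in dendritic cells, 10 to 85 in CD4 T cells, 5 to 2 in regulatory T cells and 1 to 6 in NK cells. Counts moved for both against ICB from 156 to 0 in microglia, 5 to 0 in dendritic cells, 17 to 0 in CD8 T cells, 21 to 3 in CD4 T cells and 46 to 24 in regulatory T cells. Counts moved for both against none from 789 to 7 in microglia, 1 to 0 in dendritic cells and 26 to 12 in regulatory T cells. Counts moved for the interaction from 1 to 0 in dendritic cells, 4 to 1 in CD8 T cells, 0 to 1 in CD4 T cells, 6 to 1 in regulatory T cells and 2 to 0 in NK cells. In this setting the number of class shares passing went from 1 to 2 for ICB and from 1 to 2 for both against none. There too the microglia share went for ICB from 1.31 to 1.69 (edgeR adjusted p = 0.0560 to 0.0173) and for both against none from 2.29 to 2.76 (edgeR adjusted p = 0.0510 to 0.0201). The sign turned for H2-Eb1 in CD8 T cells for ICB (from −0.85 to 0.12), Apoe in dendritic cells for both against ICB (from 1.52 to −0.023), C1qb in CD8 T cells for both against ICB (from 1.2 to −1.55), Jmy in CD4 T cells for both against ICB (from 1.24 to −0.16) and Apoe in dendritic cells for both against none (from 1.36 to −0.60).

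With the contrast averaged in the 4-group model gene counts moved for PT2385 from 5 to 27 in microglia, 125 to 50 in macrophages and 12 to 26 in CD8 T cells. For ICB counts went from 1 to 3 in dendritic cells and 1 to 6 in NK cells. Without cluster M17 gene counts moved for PT2385 from 5 to 0 in microglia. The shifts for both against ICB were from 156 to 65 in microglia. The shifts for both against none were from 789 to 484 in microglia. In cluster M10 alone gene counts moved for ICB from 1768 to 52 in microglia. For both against ICB they moved from 156 to 14 in microglia. For both against none they moved from 789 to 32 in microglia. For the interaction they moved from 0 to 4 in microglia. The sign turned for Ccr1 in microglia for PT2385 (from −1.09 to 0.33), Napsa in microglia for PT2385 (from −1.11 to 1.19), Gpr141 in microglia for ICB (from −2.96 to 1.54), Nrg1 in microglia for ICB (from −3.03 to 0.56), Acp5 in microglia for both against ICB (from −2.36 to 0.47) and Pde7b in microglia for both against none (from −3.58 to 0.70). With the strict cell filter gene counts moved for ICB from 1 to 2 in dendritic cells and 5 to 10 in regulatory T cells. The counts for both against ICB went from 46 to 29 in regulatory T cells. The counts for the interaction went from 4 to 1 in CD8 T cells and 2 to 1 in NK cells. In this setting the number of class shares passing went from 1 to 2 for ICB and from 1 to 2 for both against none. There too the microglia share went for ICB from 1.31 to 1.38 (edgeR adjusted p = 0.0560 to 0.0487) and for both against none from 2.29 to 2.39 (edgeR adjusted p = 0.0510 to 0.0391). Without cluster M15 gene counts moved for ICB from 1 to 0 in dendritic cells. Both against ICB gave shifts from 5 to 2 in dendritic cells. Both against none gave shifts from 1 to 0 in dendritic cells. The interaction gave shifts from 1 to 3 in dendritic cells. The sign turned for Apoe in dendritic cells for both against ICB (from 1.52 to −0.98), Trem2 in dendritic cells for both against ICB (from 1.55 to −0.08), Apoe in dendritic cells for both against none (from 1.36 to −0.57) and Apoe in dendritic cells for the interaction (from 1.88 to −1.1).

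With only the 4 libraries given ICB gene counts moved for both against ICB from 5 to 3 in dendritic cells, 17 to 0 in CD8 T cells, 21 to 2 in CD4 T cells and 33 to 14 in NK cells. With the summed effects of the additive model gene counts moved for both against none from 1 to 2 in dendritic cells and 27 to 17 in NK cells. Without the CD8 T cell cluster led by Gzmf gene counts moved for both against ICB from 17 to 11 in CD8 T cells. The shifts for both against none were from 17 to 4 in CD8 T cells. The shifts for the interaction were from 4 to 1 in CD8 T cells. Without cluster T15 gene counts moved for PT2385 from 43 to 22 in regulatory T cells. For ICB they moved from 5 to 16 in regulatory T cells. For both against ICB they moved from 46 to 19 in regulatory T cells. For the interaction they moved from 6 to 2 in regulatory T cells. The sign turned for Upp1 in regulatory T cells for both against ICB (from 2.09 to −0.54).

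With RLE size factors gene counts moved for ICB from 5 to 8 in regulatory T cells. Over the classes with a mean of at least 10 cells the number of class shares passing went from 1 to 2 for ICB and from 1 to 2 for both against none. There too the microglia share went for ICB from 1.31 to 1.31 (edgeR adjusted p = 0.0560 to 0.0354) and for both against none from 2.29 to 2.29 (edgeR adjusted p = 0.0510 to 0.0282). With named immune classes as the denominator the microglia share went for ICB from 1.31 to 1.44 (edgeR adjusted p = 0.0560 to 0.0414) and for both against none from 2.29 to 2.52 (edgeR adjusted p = 0.0510 to 0.0294). With TMM factors it did not pass for ICB (1.26, edgeR adjusted p = 0.110) or both against none (2.46, edgeR adjusted p = 0.0574). Nor did it with doublets kept (1.23 and 2.10, edgeR adjusted p = 0.0707 and 0.0659). The exact permutation test gave the microglia share an adjusted p of 0.419 for ICB. By the exact permutation test the number of class shares passing went from 1 to 0 for ICB. With an estimated correlation the gene lists passing went from 55 to 0 for PT2385, from 62 to 0 for ICB, from 57 to 0 for both against ICB and from 57 to 0 for both against none. With the rotation test fry the gene lists passing went from 55 to 5 for PT2385, from 62 to 1 for ICB, from 57 to 0 for both against ICB and from 57 to 10 for both against none.

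Each library was left out in turn, where the contrast could still be fitted. The lowest and highest gene counts follow, with the pool whose loss gave the highest. For PT2385 they were 2 to 156 in microglia (without the untreated pool), 0 to 1160 in macrophages (without ICB pool 2), 0 to 32 in dendritic cells (without ICB pool 2), 7 to 47 in CD8 T cells (without combination pool 2), 4 to 24 in CD4 T cells (without ICB pool 2), 15 to 45 in regulatory T cells (without ICB pool 2) and 17 to 125 in NK cells (without ICB pool 1). For ICB they were 89 to 2695 in microglia (without ICB pool 2), 0 to 31 in macrophages (without ICB pool 1), 0 to 4 in dendritic cells (without PT2385 pool 2), 2 to 15 in CD8 T cells (without combination pool 2), 6 to 27 in CD4 T cells (without combination pool 1), 1 to 51 in regulatory T cells (without ICB pool 2) and 0 to 12 in NK cells (without PT2385 pool 2). For both against ICB they were 12 to 251 in microglia (without ICB pool 1), 0 to 1583 in macrophages (without ICB pool 2), 0 to 64 in dendritic cells (without ICB pool 2), 2 to 120 in CD8 T cells (without combination pool 1), 3 to 322 in CD4 T cells (without combination pool 2), 31 to 114 in regulatory T cells (without ICB pool 2) and 11 to 93 in NK cells (without ICB pool 2). For both against none they were 143 to 791 in microglia (without ICB pool 1), 0 to 353 in macrophages (without ICB pool 1), 0 to 4 in dendritic cells (without PT2385 pool 1), 12 to 88 in CD8 T cells (without combination pool 1), 9 to 116 in CD4 T cells (without combination pool 2), 11 to 52 in regulatory T cells (without ICB pool 2) and 7 to 63 in NK cells (without ICB pool 2). For the interaction they were 0 to 40 in macrophages (without ICB pool 2), 0 to 3 in dendritic cells (without ICB pool 2), 2 to 101 in CD8 T cells (without combination pool 1), 0 to 63 in CD4 T cells (without combination pool 2), 4 to 22 in regulatory T cells (without ICB pool 2) and 0 to 13 in NK cells (without ICB pool 2). The share of choroid-led cells ran from 5.29 to 6.99 for ICB. For both against none the fits gave 11.83 to 12.62, which are model values against a library with 0 such cells and not a measured fold.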

Other observations

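Tests in this part on single clusters or single genes outside the naming rule were chosen after the result was seen.

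Clusters of monocyte/macrophage-like cells differed in share between libraries, which was not tested. Cluster M8, with Nos2, Arg1 and Saa3, made up 27.5% and 19.9% of the class in the pools given PT2385 alone, 6.1% in the untreated library, 4.1% and 5.9% with ICB and 6.0% and 13.5% with both. Nos2 itself stood at 57.1 and 194 CPM in the combination pools and at 9.86 and 20.0 with ICB. Cluster M2 made up 20.9% and 21.1% with PT2385 and 22.0% and 27.8% with both, against 10.4% in the untreated library and 3.5% and 18.2% with ICB. Cluster M0 made up 28.2% of the class in the untreated library, 4.1% and 5.9% with PT2385, 9.2% and 19.3% with ICB and 15.3% and 7.4% with both.

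Within the homeostatic microglia cluster M10, several transcripts that are not microglia identity genes fell with both treatments against none. Adamts1, a matrix protease gene, fell by 2.10 (edgeR adjusted p = 4.58e-05), the signalling regulator Rgs1 by 1.38 (edgeR adjusted p = 5.18e-04), and the clock genes Per1 and Cry1 by 1.05 and 1.09 (edgeR adjusted p = 0.00826 and 0.0361). The adhesion gene Icam1 rose by 1.04 (edgeR adjusted p = 0.0361). With ICB, Icam1 rose by 0.79 (edgeR adjusted p = 0.00503) and the lipid droplet gene Plin2 fell by 0.80 (edgeR adjusted p = 0.0344) in M10.

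Once cluster T15 is left out, Gzmb fell in regulatory T-like cells by 1.05 for PT2385, 0.80 for ICB (edgeR adjusted p = 2.93e-05), 1.02 for both against ICB (edgeR adjusted p = 1.23e-04) and 1.87 for both against none. These comparisons share libraries and are not separate evidence. As a hypothesis, PT2385 and ICB may each lower granzyme B in regulatory T cells. In the whole class only the fall with PT2385 passed, and the value for ICB was −0.59 (edgeR adjusted p = 0.449). Intracellular staining of granzyme B in FOXP3-positive cells of the 4 groups would test this.

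Pools of 1 group differed in their gene counts. Summed over all cells, chi-square per degree of freedom over genes between the 2 pools was 20.2 with PT2385, 141 with ICB and 35.1 with both, against 71.1 to 408 between libraries of different groups. The ICB pools were unlike each other. ICB pool 2 lay closer to the untreated library (97.7) and to the PT2385 pools (105 and 91.2) than to ICB pool 1. From the combination pools it lay farther (157 and 224). UMIs of 1 cell are not independent, so these values have no fixed level under chance. Shares over named immune cells put microglia-like cells at 35.0% and 44.6% in the combination pools.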
